A study of Mus musculus with 18 samples.

How the data were processed

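RNA sequencing of primary tail-tip fibroblasts and of postnatal day 1 spleen, liver and brain of female mice was re-analysed from the deposited gene tables, with 18 samples in 8 groups of 2 or 3. Per the labels, mutants carried an Xist deletion on both X chromosomes and controls on a single one, and the replicates were biological. The control columns of the deposited tables are named WT, while the labels give the heterozygous deletion, and the labels were followed. Per the labels, Trizol-extracted total RNA was depleted of ribosomal RNA with RiboMinus and sequenced with reads of 50 nt on HiSeq 2000 or 2500 instruments, and reads were mapped to GRCm38. Per the submitters' processing notes, reads in genes were counted with HTSeq 0.6.1 and normalized with edgeR, whose version is not given in the sources used here. The aligner, the annotation release and whether counting used strand are not given in the sources used here either. The deposited values are the authors' scaled counts, called signal here, in 4 tables, 1 per tissue, each normalized on its own. They lie on the scale of TMM-scaled CPM, with column sums that differ between libraries. In each column 100% of nonzero values were whole multiples of the smallest step at a tolerance of 0.05, so whole read counts were recovered from them.

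Reads in genes ranged from 12.4 M to 29.2 M per library, and 1 read had a signal of 0.0343 to 0.0751. A gene with no read could have held up to 3 reads at 95% confidence, a signal of 0.103 to 0.225. These limits cover counting error only. Replicates differed by more than counting error, with a chi-square per degree of freedom of 8.84 to 165. Each table held 46078 gene identifiers, of which 45229 were matched to GENCODE mouse release 21 (GRCm38) for names and coordinates and 849 were not. The unmatched identifiers held at most 0.179% of a library's reads and were left out of the tests.

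The choices below were made before the data were examined, unless stated otherwise. Within each tissue, log2(signal + 0.5) of genes with a table mean of at least 1, the settings planned for CPM, was fitted with limma 3.58.1 (trend, empirical Bayes) in R 4.3.3, mutant against control, two-sided, with Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0, planned as an alternative on recovered reads, called 3, 182, 211 and 41 genes in fibroblasts, spleen, liver and brain. The test planned for tables of raw counts was edgeR 4.0.16 (quasi-likelihood). It was run on the recovered reads after the limma counts were seen, and called 0, 0, 0 and 4 genes. DESeq2 values of single genes were also added after. X-linked genes without Xist were compared as a set with autosomal genes by camera with a preset correlation of 0.01 and by camera with an estimated correlation. They were also tested against no change by fry, which makes no comparison with autosomal genes. Camera with an estimated correlation takes its degrees of freedom from the few libraries, so it passes less easily whatever the correlation. The mean X-linked level of each library, relative to the 19 autosomes, was compared by exact permutation, whose smallest p is 0.333 for 2 against 2 libraries and 0.1 for 3 against 3. The X-linked responses of 6 tissue pairs were compared by permuting labels within tissues. Escape genes were compared with 10000 random sets of other X-linked genes of like expression. Each chromosome and each 10 Mb window of the X was summarized by its median. 45 gene lists of X-linked classes, cell types and processes, fixed in advance, were tested by camera where at least 5 members were tested, adjusted over the lists of a tissue.

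The genes named are Xist, the tested genes of the inactivation centre and escape lists, up to 4 members with the smallest p of each other list, and in each tissue the 10 X-linked and 10 autosomal genes with the largest fold change among those past the threshold with separated groups and a mean of at least 5. Where fewer than 5 passed, the 5 with the smallest p that met the other criteria were named. Other genes named were chosen after their values were seen.

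On simulated counts with the dispersion of each tissue and 200 changed genes, limma recovered 29, 6, 5 and 90 of 100 genes changed 2-fold in fibroblasts, spleen, liver and brain, and 95, 77, 79 and 100 of 100 changed 4-fold, with 4, 4, 3 and 10 false calls. DESeq2 recovered 40, 9, 14 and 90 of the 2-fold changes with 21, 9, 19 and 9 false calls. It thus made more false calls than limma in fibroblasts, spleen and liver, so DESeq2 calls there that limma did not share are less certain. A simulated X-linked shift of 0.15 was estimated at 0.13, 0.18, 0.10 and 0.14, and with no shift camera at the preset correlation gave p = 0.905, 0.875, 0.194 and 0.729. The simulated genes were independent, with a dispersion set by expression level alone and no outlying library. The real libraries were harder, since limma did not pass Xist at 11.6-fold lower in fibroblasts. The simulation therefore cannot show that camera at the preset correlation holds its error rate in these data.

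Alternatives were pseudocounts of 0.05 and 5, a minimum mean of 5 or none, an adjusted p of 0.1, size factors by median of ratios over all or autosomal genes, limma without a trend, protein-coding genes only, the replicate number as a block, X-linked genes without escape and inactivation centre genes, and each library left out in turn. A minimum mean of 20 and lists of glucocorticoid, fasting, fat oxidation and satellite-repeat genes were added after the values were seen. Lists of clock genes were also added after the data were examined, with the prediction for them written before its test. The 4 tables were not joined, because each was normalized on its own.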

Results

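RNA of female mice was sequenced to ask what happens to X-linked genes when Xist is missing. Xist is the long noncoding RNA that coats an X chromosome in each female cell and silences most of its genes. Mutants carried an Xist deletion on both X chromosomes, and controls carried it on a single X chromosome and kept an intact copy. Primary fibroblasts grown from tail tips gave 3 control and 3 mutant libraries. Spleen, liver and brain, taken on postnatal day 1, each gave 2 control and 2 mutant libraries, for 18 libraries in all. Reads in genes numbered 18.5 M to 23.3 M per fibroblast library, 12.4 M to 18.9 M per spleen library, 15.8 M to 29.2 M per liver library and 15.3 M to 23.1 M per brain library. Gene levels are given as signal, the authors' scaled count per gene, with the SD and the number of libraries.

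Xist (ENSMUSG00000086503, X 103460366 to 103483254, minus strand, GRCm38) was lower in each mutant library than in each control library of its tissue. In brain its signal fell from 674 ± 12.1 (SD, n = 2) in controls to 3.88 ± 0.373 (SD, n = 2) in mutants, 174-fold lower (log2 fold change -7.27, SE 0.12, limma adjusted p = 1.5e-08). Spleen controls read 1205 and 1121 and spleen mutants 116.6 and 51.3, 13.9-fold lower (log2 fold change -3.90, SE 0.43, limma adjusted p = 0.136). In liver Xist read 593.6 and 730.4 in controls and 177.6 and 256.7 in mutants, 3.05-fold lower (log2 fold change -1.62, SE 0.30, limma adjusted p = 0.454) and at 32.8% of the control mean. Fibroblast controls 1 to 3 read 141.2, 98.2 and 70.5 and mutants 1 to 3 read 11.0, 13.5 and 2.33, 11.6-fold lower (log2 fold change -3.70, SE 0.63, limma adjusted p = 0.9997). DESeq2 on the recovered reads, a test chosen after the limma result was seen, passed Xist in spleen (adjusted p = 3.8e-14), liver (adjusted p = 8.9e-05) and fibroblasts (adjusted p = 3.0e-05). Leaving out spleen mutant 1 or spleen mutant 2 brought the limma adjusted p there to 7.0e-08 or 0.0016, and leaving out control 1 or control 2 to 0.485 or 0.0572. Mutant means stood at 0.576% of control means in brain, 7.22% in spleen, 8.66% in fibroblasts and 32.8% in liver. Which part of Xist was deleted is not given in the sources used here, so the source of the reads left cannot be told. Near-complete loss was seen in brain only, which limits comparisons of X-linked genes between tissues. The Y-linked gene Ddx3y had no read in any library, which allows a signal of up to 0.225 in the shallowest, spleen mutant 1. Kdm5d, also Y-linked, gave 0.638 to 1.40 in the 6 fibroblast libraries and at most 0.0402 in the 12 organ libraries.

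**Figure D1:**
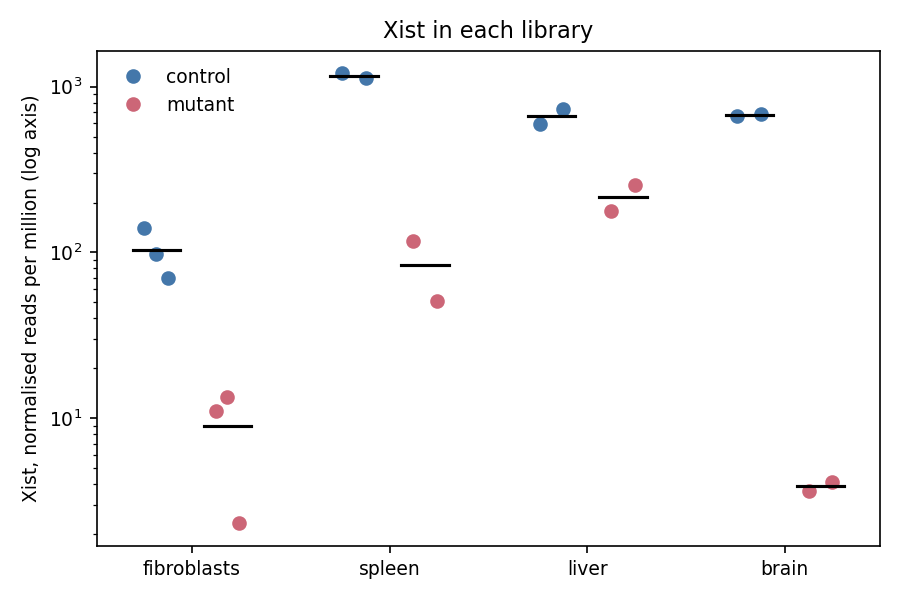
Xist signal in each library on a log axis, controls and mutants side by side for fibroblasts, spleen, liver and brain, with a bar at each group mean. Mutant brain libraries sit at 3.62 and 4.15 against 665.6 and 682.7 in controls, while mutant liver libraries stay at 177.6 and 256.7.

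In mutant brain, X-linked genes ran higher as a group. Of 610 tested X-linked genes, 452 (74.1%) lay above 0, against 45.0% of 16289 autosomal genes, and the median log2 fold change was 0.14 for X-linked and -0.02 for autosomal genes. The difference of 0.16 amounts to 11.9%, well short of a doubling. X-linked genes took 3.11% and 3.09% of reads in control brains and 3.62% and 3.57% in mutant brains. Among the X-linked genes with the smallest p were Usp9x, a deubiquitinase, at 353 ± 25.6 in controls and 609 ± 32.4 in mutants (SD, n = 2 each), Pak3, a neuronal kinase, at 313 ± 5.24 and 488 ± 16.5, and Med14, a Mediator subunit, at 86.5 ± 4.42 and 142 ± 10.9. Armcx4 read 108 ± 2.82 and 183 ± 8.17, and Tmem164 read 56.6 ± 2.31 and 92.3 ± 1.08. By limma these 5 genes had log2 fold changes of 0.64 to 0.79 with adjusted p of 0.107 to 0.161, and no X-linked gene besides Xist passed alone. DESeq2 on the recovered reads called 23 X-linked genes other than Xist in brain, each higher, with Usp9x at adjusted p = 1.4e-07 and Armcx4 at 5.9e-06, against 13 autosomal genes higher and 4 lower (Fisher's exact p = 2.2e-23 for the share of genes called). The X-linked share of DESeq2 calls was lower than the autosomal share in liver (1 X-linked gene higher, against 143 autosomal genes higher and 66 lower; Fisher's exact p = 0.011), and Fisher's exact p was 0.837 in spleen and 0.0661 in fibroblasts. Genes are not independent replicates, so these Fisher's exact p-values describe these libraries only. As a set in brain, X-linked against autosomal genes passed camera (p = 1.1e-21) and camera with an estimated correlation (p = 0.0059). Against no change rather than against autosomal genes, X-linked genes in brain gave p = 0.0062 by fry, which allows for correlation among genes. X-linked genes with both mutants above both controls made up 41.8% of the set and those with both below made up 6.72%, where chance gives 16.7% each way, and autosomal genes gave 12.7% and 16.6%.

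Per library, the mean X-linked level relative to autosomal genes was -0.07 and -0.11 in control brains and 0.10 and 0.08 in mutant brains on the log2 scale, a difference of 0.18 (exact permutation p = 0.333, the smallest that 2 against 2 libraries can give). Within the libraries numbered 1 and 2 the difference was 0.17 and 0.20. In brain the excess was present at each level of expression, at 0.12 for genes with a mean signal of 1 to 5 and 0.18 for those of 100 and over.

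**Figure D2:**
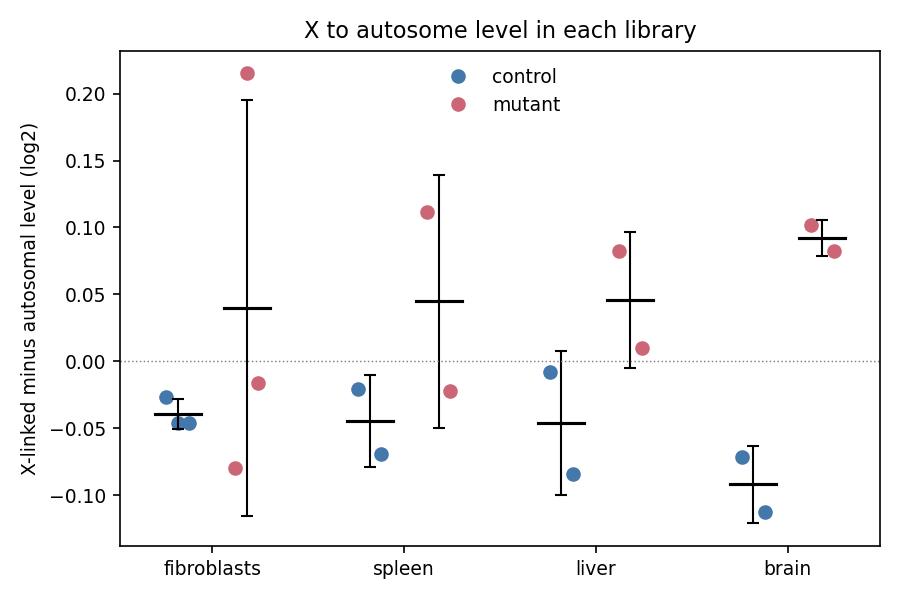
Mean log2 level of X-linked relative to autosomal genes in each library, with each gene set to 0 at its mean in the tissue's table, for controls and mutants of the 4 tissues, with bars at the mean and SD. Both mutant brains lie at 0.10 and 0.08, above both controls, and in fibroblasts mutant 2 lies at 0.22 while mutants 1 and 3 lie at -0.08 and -0.02.

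In mutant fibroblasts X-linked genes lay slightly above autosomal genes, and mutant 2 carried the excess. Of 440 tested X-linked genes 265 (60.2%) lay above 0, against 48.5% of 12623 autosomal genes, and the medians of 0.05 and -0.00 differed by 0.05 on the log2 scale, or 3.65%. Utp14a, a nucleolar protein of ribosome assembly, read 33.3 ± 2.09 in controls and 51.0 ± 1.14 in mutants (SD, n = 3 each; log2 fold change 0.61, SE 0.10, limma adjusted p = 0.9997), and DESeq2 passed it (adjusted p = 0.0033). The palmitoyltransferase Zdhhc9 read 61.2 ± 4.92 and 89.4 ± 5.34, Tmem164 read 52.8 ± 2.29 and 101 ± 22.9, Rbm41 read 9.03 ± 0.56 and 13.4 ± 1.17, and Tbl1x, a corepressor subunit, read 146 ± 3.95 and 185 ± 9.41. The set passed camera (p = 3.2e-05) but not camera with an estimated correlation (p = 0.105), and fry, against no change, gave p = 0.278 with correlation among genes allowed for. Per library the X-linked level was -0.03, -0.05 and -0.05 in controls 1 to 3 and -0.08, 0.22 and -0.02 in mutants 1 to 3, a difference of 0.08 (exact permutation p = 0.7; 0.1 is the smallest that 3 against 3 can give), and within numbers 1, 2 and 3 it was -0.05, 0.26 and 0.03. Without mutant 2 the set difference was 0.01 (camera p = 0.558 at the preset correlation), and without mutant 1 it was 0.12. With no filter on low values it was 0.00 (camera p = 0.393 at the preset correlation).

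In mutant liver 329 of 503 X-linked genes (65.4%) lay above 0, against 55.6% of 14554 autosomal genes, with medians of 0.10 and 0.04 and a difference of 0.05 (3.86%). Tsc22d3, a glucocorticoid-induced transcriptional regulator, read 17.1 ± 2.10 in controls and 83.5 ± 40.4 in mutants (SD, n = 2 each; log2 fold change 2.17, SE 0.38, limma adjusted p = 0.454; DESeq2 adjusted p = 2.6e-04). Tlr8, a sensor of single-stranded RNA, read 3.15 ± 0.133 and 8.24 ± 0.929, Elk1, a transcription factor, 15.3 ± 0.913 and 32.0 ± 6.08, and Utp14a 25.6 ± 2.26 and 56.3 ± 11.3. The liver set passed camera (p = 0.028) but not camera with an estimated correlation (p = 0.0717). In liver fry, which allows for correlation among genes, gave p = 0.013 against no change, where autosomal genes also lay above 0, so this does not show a difference from them. Without control 2 the liver difference was 0.01 (camera p = 0.329 at the preset correlation), without mutant 1 it was 0.05 (camera p = 0.17), and without control 1 or mutant 2 it was 0.13 or 0.12. With no filter on low values it was 0.00 (camera p = 0.717 at the preset correlation), and without escape and inactivation centre genes 0.04 (camera p = 0.0629). Per library the level was -0.01 and -0.08 in control livers and 0.08 and 0.01 in mutant livers (difference 0.09, exact permutation p = 0.333), and within numbers 1 and 2 the difference was 0.09 and 0.09.

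In mutant spleen 306 of 571 X-linked genes (53.6%) lay above 0, against 43.1% of 15993 autosomal genes, with medians of 0.03 and -0.08 and a difference of 0.11 (7.59%). Tsc22d3 read 53.1 ± 13.7 in controls and 261 ± 24.3 in mutants (SD, n = 2 each; log2 fold change 2.31, SE 0.30, limma adjusted p = 0.178; DESeq2 adjusted p = 8.5e-08). Tlr7, another sensor of single-stranded RNA, read 12.4 ± 4.66 and 36.5 ± 2.29 (DESeq2 adjusted p = 0.016), and Nrk, Capn6 and Shroom2 had log2 fold changes of 1.57, 1.45 and 1.49 (DESeq2 adjusted p = 0.0135, 0.023 and 0.0137). The spleen set passed camera (p = 0.034) but not camera with an estimated correlation (p = 0.166), and fry, against no change, gave p = 0.161 with correlation among genes allowed for. Without mutant 1 the difference was 0.03 (camera p = 0.787 at the preset correlation) and without control 2 it was 0.08 (camera p = 0.323). With no filter on low values it was 0.02 (camera p = 0.0929 at the preset correlation), and without escape and inactivation centre genes 0.10 (camera p = 0.0583). Per library the level was -0.02 and -0.07 in control spleens and 0.11 and -0.02 in mutant spleens (difference 0.09, exact permutation p = 0.667), and within numbers 1 and 2 the difference was 0.13 and 0.05. Spleen mutant 1, the library with the highest X-linked level, also stood apart with 3.01% of its reads in satellite-repeat genes (0.0184% in mutant 2) and reads in 32381 genes (25166 to 26940 in the other spleens).

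Among 20 chromosomes the X had the highest median log2 fold change in each tissue. Its camera test, adjusted over the chromosomes, passed in brain (adjusted p = 2.6e-20) and fibroblasts (adjusted p = 6.2e-04) but not in liver (adjusted p = 0.558) or spleen (adjusted p = 0.681). In fibroblasts the X as a set did not pass with an estimated correlation (p = 0.105) or without mutant 2 (p = 0.558 at the preset correlation). In brain the next chromosome, 14, had a median of -0.00. Along the X in windows of 10 Mb, brain medians were highest at 10 to 20 Mb (0.30 over 30 genes), 40 to 50 Mb (0.30 over 26 genes) and 140 to 150 Mb (0.25 over 33 genes). The 60 to 70 Mb window was at -3.2e-05, over only 19 genes. The spleen window at 70 to 80 Mb, with 78 genes, had a median of -0.15. The X-linked responses of pairs of tissues differed by -0.10 to -0.00 in the per-library level (exact permutation p of 0.433 to 0.944, 6 pairs, adjusted p = 0.944 for each; the smallest p possible was 0.0167 with fibroblasts and 0.0556 between organs), so a stronger response in brain than in another tissue was not shown. Across genes, which are not independent replicates, the log2 fold changes of X-linked genes had a Spearman correlation of 0.45 between fibroblasts and brain, 0.43 between liver and brain, 0.35 between spleen and brain, 0.25 between spleen and liver, 0.24 between fibroblasts and liver and 0.12 between fibroblasts and spleen. Autosomal genes gave 0.08, 0.21, 0.13, 0.20, 0.00 and -0.03 for the same pairs.

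**Figure D3:**
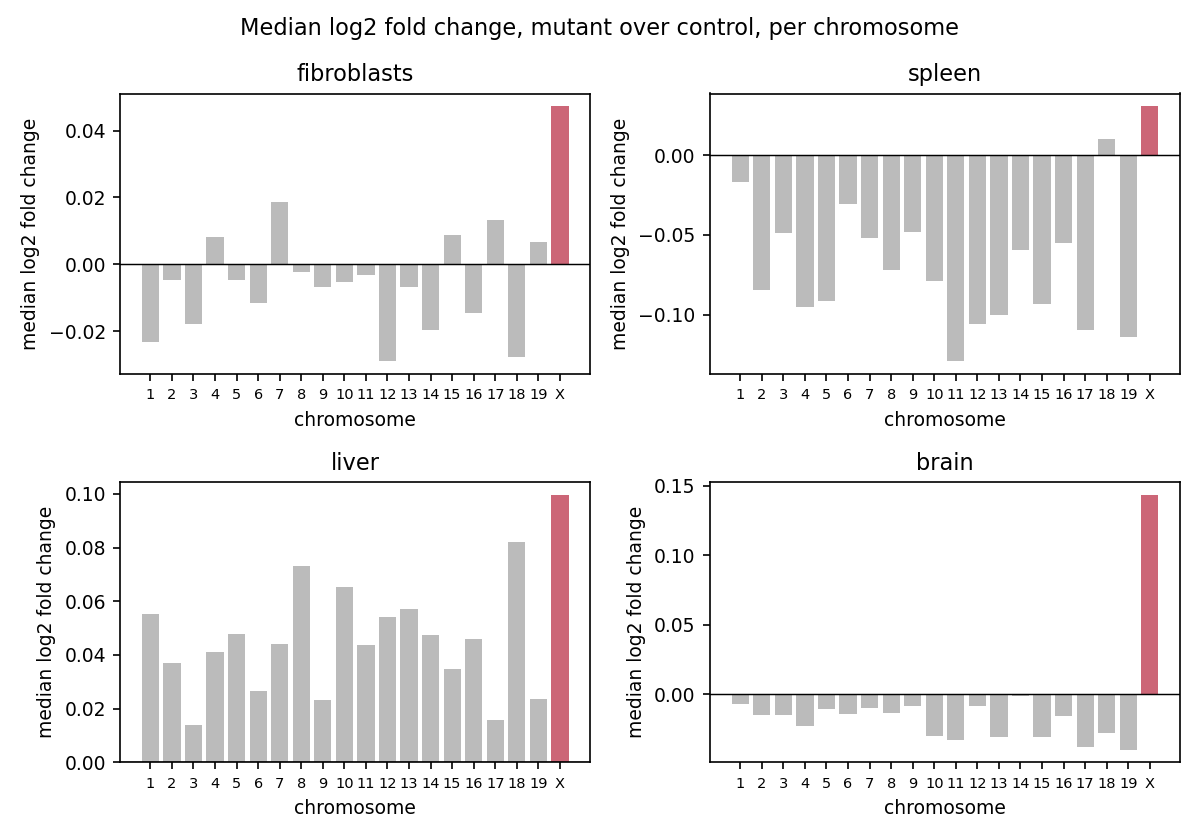
Median log2 fold change, mutant against control, of the tested genes of each autosome and of the X without Xist, in the 4 tissues. The X stands highest in each tissue, at 0.14 in brain, 0.10 in liver, 0.05 in fibroblasts and 0.03 in spleen.

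**Figure D4:**
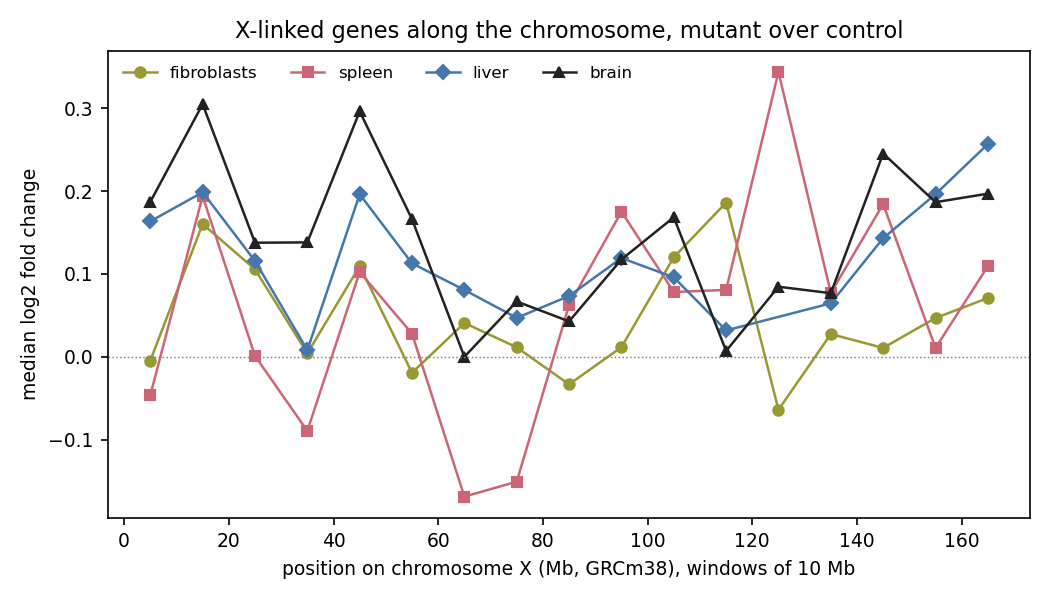
Median log2 fold change of tested X-linked genes in 10 Mb windows along the X in the 4 tissues, plotted at the middle of each window with at least 5 genes. In brain the medians are highest at 10 to 20 Mb (0.30) and 40 to 50 Mb (0.30).

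Genes that escape X inactivation, and are read from both X chromosomes in normal females, lay higher than other X-linked genes in mutants of the 4 tissues. Taking escape genes outside the inactivation centre, medians were 0.45 in brain (15 of 16 genes above 0), 0.42 in liver (15 of 15), 0.24 in spleen (11 of 16) and 0.17 in fibroblasts (13 of 16), against 0.13, 0.09, 0.02 and 0.04 for other X-linked genes. Among 10000 random sets of other X-linked genes of like expression these medians stood at percentiles 100, 99.9, 97.8 and 99.4, which describes these libraries only. The histone demethylases Kdm5c and Kdm6a had log2 fold changes of 0.44 (SE 0.10) and 0.45 (SE 0.11) in brain, 0.35 and 0.52 in liver and 0.25 and 0.35 in fibroblasts, but -0.14 (SE 0.30) and -0.23 (SE 0.32) in spleen. The RNA helicase Ddx3x had 0.44 in brain, 0.40 in liver, 0.23 in spleen and 0.18 in fibroblasts. Usp9x had 0.73 (SE 0.22) in liver, 0.42 in spleen and 0.31 in fibroblasts, and 1810030O07Rik had 0.83, 0.85, 0.77 and 0.58 in brain, liver, spleen and fibroblasts. Pbdc1 and Syap1 had 0.76 (SE 0.16) and 0.60 (SE 0.13) in brain. None of these single genes passed limma over all genes, and DESeq2 called Usp9x and 1810030O07Rik in brain (adjusted p = 1.4e-07 and 0.0011). By camera the full escape list was set against all tested genes, not against other X-linked genes. It passed in brain (17 of 18 above 0, camera adjusted p = 2.9e-24, or 0.405 with an estimated correlation), where 13 of its genes passed when adjusted over the list alone. It passed in fibroblasts (15 of 18, adjusted p = 1.6e-10; 0.0595 with an estimated correlation; 1 gene adjusted over the list alone), liver (17 of 17, adjusted p = 7.1e-05; 0.815 with an estimated correlation) and spleen (13 of 18, adjusted p = 0.0129; 0.763 with an estimated correlation), the last 2 with 0 genes adjusted over the list alone by limma. The spleen call was lost without control 2 (median 0.11, adjusted p = 0.519) or mutant 1 (0.17, adjusted p = 0.405), with control 1 left out the spleen median was 0.40, and without fibroblast mutant 1 the fibroblast median was 0.28. The gap to other X-linked genes was 0.52 in liver without control 1, and 0.45 and 0.11 in spleen without control 1 and control 2.

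**Figure D5:**
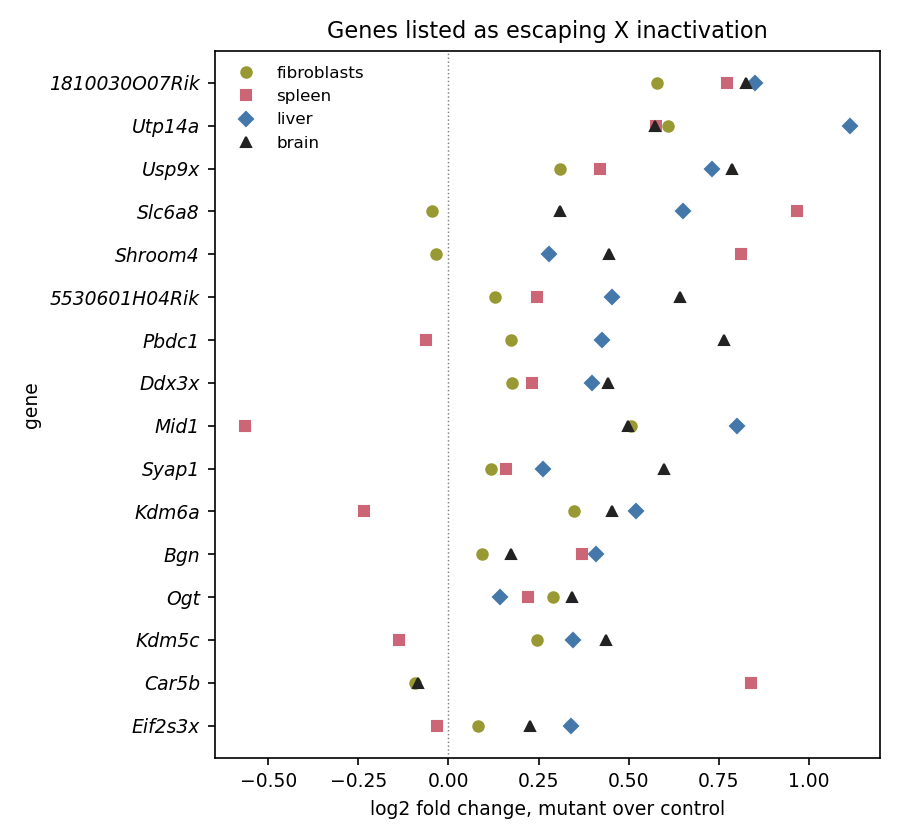
Log2 fold change, mutant against control, of each of 16 escape genes in the 4 tissues, with a dotted line at 0. Usp9x lies at 0.79 in brain, 0.73 in liver, 0.42 in spleen and 0.31 in fibroblasts, while Kdm6a lies at -0.23 in spleen.

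The neighbours of Xist in the X inactivation centre were higher in mutant brain. Ftx, a noncoding RNA that promotes Xist expression, read 20.1 ± 2.25 in controls and 34.9 ± 0.0148 in mutants (SD, n = 2 each; log2 fold change 0.78, SE 0.14, limma adjusted p = 0.283; DESeq2 adjusted p = 0.0116). Jpx, another noncoding activator of Xist, read 9.0 ± 0.606 and 15.7 ± 4.05. Rlim, a ubiquitin ligase that promotes Xist expression, read 120 ± 3.80 and 138 ± 5.93. With Xist counted, 6 of 7 tested members lay above 0 in brain, where 3 rose and 1, Xist, fell when adjusted over the list alone, against 1 over all genes. The list's median was 0.31 and its mean -0.65. Camera, against all tested genes, called it higher (adjusted p = 0.0149, or 0.56 with an estimated correlation). The call was lost without any of control 1, control 2, mutant 1 or mutant 2 (adjusted p = 0.136, 0.0922, 0.0854 and 0.768). Whether counting used strand is not given in the sources used here, so reads of Xist and its antisense partner Tsix cannot be told apart.

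Other X-linked lists fixed by function were also higher in mutant brain, where X-linked genes as a whole had a median of 0.14. Camera set each list against all tested genes, most of them autosomal, so the shift of the whole X could account for these calls. The lists were not compared with other X-linked genes. Chromatin and transcription genes had 24 of 26 members above 0 (median 0.22, camera adjusted p = 6.1e-17; 0.405 with an estimated correlation), and 7 rose when adjusted over the list alone, against 0 over all genes by limma. Among them Smarca1, a chromatin remodeller, had a log2 fold change of 0.38 (SE 0.11) and Hdac6, a deacetylase, 0.43 (SE 0.12). Brain-related X-linked genes had 25 of 33 above 0 (median 0.10, adjusted p = 1.1e-05; 0.42 with an estimated correlation), with Armcx2 at 0.54 (SE 0.10) and Armcx1 at 0.62 (SE 0.12). 3 of them rose adjusted over the list alone. Without control 2 this call was lost (median 0.08, adjusted p = 0.0635), and without control 1 the median was 0.15. X-linked housekeeping genes had 25 of 31 above 0 (median 0.16, adjusted p = 1.7e-05; 0.56 with an estimated correlation), a call lost without mutant 2 (median 0.11, adjusted p = 0.056) and with a median of 0.09 without control 2. X-linked blood and immune genes had 14 of 15 above 0 (median 0.22; 0.33 without control 2), liver-related ones 12 of 14 (median 0.29) and growth suppressors 11 of 16 (median 0.16), with adjusted p = 1.1e-05, 1.5e-05 and 6.0e-05, and 0.405 for each with an estimated correlation. Adjusted over the list alone, 0, 1 and 1 of their genes rose.

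The X-linked lists of the other tissues were likewise set against all tested genes, not against other X-linked genes. In mutant liver, X-linked blood and immune genes had 19 of 22 members above 0 (median 0.29, camera adjusted p = 2.7e-04, or 0.815 with an estimated correlation). Of them 2 rose when adjusted over the list alone. X-linked chromatin genes had 24 of 26 above 0 in liver (median 0.28, adjusted p = 0.0066; 0.815 with an estimated correlation), with the transcription factor Zfx at 0.62 (SE 0.20). That call was lost without control 2 (0.28, adjusted p = 0.25) or mutant 1 (0.25, adjusted p = 0.101). In mutant spleen, blood and immune genes on the X had 15 of 23 above 0 (median 0.20, adjusted p = 0.0129; 0.763 with an estimated correlation), and 4 rose adjusted over the list alone. That call was lost without control 1 (-0.04) or mutant 2 (0.04), and the median was 0.62 without control 2 and 0.36 without mutant 1. X-linked brain-related genes had 21 of 26 above 0 in spleen (median 0.31, adjusted p = 0.0049; 0.763 with an estimated correlation), lost without mutant 1 (median 0.05) or control 2 (adjusted p = 0.0533), with medians of 0.21 without control 1 and 0.48 without mutant 2. Other X-linked lists had no call in spleen, with 4 of 31 housekeeping genes above 0 (median -0.22, adjusted p = 0.0538; 0.763 with an estimated correlation), 9 of 26 chromatin genes (median -0.10, adjusted p = 0.68) and 6 of 15 growth suppressors (median -0.16, adjusted p = 0.993). In mutant fibroblasts, X-linked chromatin genes had 18 of 26 above 0 (median 0.09, adjusted p = 2.1e-04; 0.772 with an estimated correlation), lost without control 3 (adjusted p = 0.0592) or mutant 2 (adjusted p = 0.472), with a median of 0.15 without mutant 1.

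Over all genes limma called 4 of 16909 tested in brain and 0 in spleen (16578 tested), liver (15075) and fibroblasts (13077). At an unadjusted p below 0.05 limma gave 688 genes in brain, 1039 in spleen, 1006 in liver and 127 in fibroblasts, where chance alone gives about 845, 829, 754 and 654. edgeR, added after the limma counts were seen, also called 4, 0, 0 and 0 (676, 1178, 1038 and 133 at an unadjusted p below 0.05). DESeq2 called 41 in brain (36 higher, 5 lower), 182 in spleen (158 higher, 24 lower), 211 in liver (144 higher, 67 lower) and 3 in fibroblasts (1 higher, 2 lower). With the replicate number as a block, limma called 356 in spleen and 60 in liver, though the numbers were not taken as pairs. The limma count was 170 or 177 in spleen without mutant 1 or mutant 2, and 109, 9 or 27 in brain without control 2, mutant 1 or mutant 2.

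Besides Xist, the 3 genes called in brain were the pseudogenes Gm4735 (0.686 ± 0.121 in controls and 13.5 ± 1.67 in mutants, SD, n = 2 each; log2 fold change 3.56, SE 0.24, limma adjusted p = 9.4e-04), Gm9493 (1.60 ± 0.136 and 17.6 ± 0.258; 3.11, SE 0.21, adjusted p = 9.4e-04) and 3110053B16Rik (0.669 ± 0.522 and 10.2 ± 0.325; 3.27, SE 0.33, adjusted p = 0.0188). Reads of pseudogenes can come from near-identical copies, so these levels are uncertain. Of genes with smaller p-values that did not pass limma, Hif3a, a hypoxia-related transcription factor, read 17.0 ± 0.0923 in control and 37.4 ± 6.60 in mutant brain (log2 fold change 1.10, limma adjusted p = 0.138; DESeq2 adjusted p = 2.9e-05). Igfbp3, a binder of insulin-like growth factors, read 40.0 ± 3.04 and 71.7 ± 4.53 (DESeq2 adjusted p = 8.6e-05), and Ccn2, a matricellular protein, 7.82 ± 0.450 and 17.5 ± 2.84 (DESeq2 adjusted p = 0.003).

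Choroid plexus and ependyma markers were higher in mutant brain, with 9 of 10 above 0 (median 0.49, camera adjusted p = 9.9e-05; 0.686 with an estimated correlation). Ttr, the thyroid hormone carrier made by the choroid plexus, read 446 ± 444 in controls and 812 ± 247 in mutants (SD, n = 2 each). Without control 1 the median was -0.03, without control 2 it was 0.98 and without mutant 2 it was 0.73. Imprinted genes had 22 of 27 above 0 (median 0.13, adjusted p = 2.3e-04; 0.56 with an estimated correlation), with Peg10 at 0.44 (SE 0.12), a call lost without control 1 (0.06, adjusted p = 0.0975) and with a median of 0.20 without control 2. Neuronal markers had 4 of 24 above 0 (median -0.10, adjusted p = 0.0149; 0.686 with an estimated correlation), lost without control 1 (-0.02, adjusted p = 0.858) and at -0.25 without control 2. Microglial markers had 3 of 9 above 0 (median -0.30, adjusted p = 0.0335; 0.659 with an estimated correlation), with P2ry12 and the fractalkine receptor Cx3cr1 at -0.71 and -0.60. That call was lost without control 2 (-0.09, adjusted p = 0.542) or mutant 1 (-0.34, adjusted p = 0.0642). None of these 4 lists had a gene past limma over all genes or adjusted over the list alone. Stress and apoptosis genes, sterol and lipid genes and mitochondrial transcripts were also called (medians -0.12, -0.15 and 0.15, adjusted p = 0.0149, 0.0335 and 0.0149, and 0.493, 0.56 and 0.493 with an estimated correlation). Without control 2 their medians were -0.10, -0.09 and 0.14 and without mutant 2 -0.21, -0.24 and 0.15, and each call was lost both times. The sterol and lipid call was also lost without control 1 (-0.09) or mutant 1 (-0.08), and the mitochondrial call without mutant 1 (0.08).

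In mutant spleen, red cell and dividing cell genes were lower and matrix, adipogenic and endothelial genes higher. Erythroid genes had 0 of 26 above 0 (median -1.13, camera adjusted p = 4.1e-08; 0.763 with an estimated correlation). The red cell membrane gene Epb42 read 485 ± 328 in controls and 136 ± 29.2 in mutants (SD, n = 2 each; DESeq2 adjusted p = 0.016). Cell cycle genes had 0 of 28 above 0 (median -0.85, adjusted p = 4.2e-10; 0.763 with an estimated correlation), with the mitotic genes Cenpf and Ccnb1 at log2 fold changes of -1.02 (SE 0.41) and -1.01 (SE 0.42). Both medians rested on control 1, at -0.20 and -0.22 without it and -2.01 and -1.47 without control 2. Neither list had a gene past limma over all genes or adjusted over the list alone. Autosomal ribosomal protein genes had 1 of 27 above 0 (median -0.28, adjusted p = 0.0049; 0.763 with an estimated correlation), lost without control 1 (-0.04) or mutant 1 (-0.10), and at -0.55 and -0.52 without control 2 and mutant 2.

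Fibroblast and matrix genes had 21 of 22 above 0 in mutant spleen (median 0.70, adjusted p = 4.2e-10; 0.763 with an estimated correlation; 0.46 without mutant 1), and 4 rose adjusted over the list alone. Lox, a collagen crosslinking enzyme, read 135 ± 8.15 in controls and 364 ± 75.7 in mutants (SD, n = 2 each; DESeq2 adjusted p = 0.0046). Adipogenic genes had 8 of 9 above 0 (median 0.50, adjusted p = 1.1e-05; 0.763 with an estimated correlation), 4 of them past the threshold adjusted over the list alone, with Pdgfra, the stromal growth factor receptor, at 127 ± 26.3 and 486 ± 43.0 (DESeq2 adjusted p = 7.7e-06) and the fatty acid binding protein Fabp4 at 10.1 ± 0.578 and 66.1 ± 42.7 (DESeq2 adjusted p = 7.7e-06). Their median was 0.96 without control 2 and 0.83 without mutant 1. Imprinted genes had 22 of 26 above 0 (median 0.58, adjusted p = 4.1e-08; 0.763 with an estimated correlation), with the growth factor Igf2 at 312 ± 85.0 and 780 ± 249 and the growth inhibitor Cdkn1c at 42.9 ± 0.903 and 98.4 ± 0.510 (DESeq2 adjusted p = 0.047 and 0.023). Endothelial genes had 11 of 12 above 0 (median 0.60, adjusted p = 1.1e-05; 0.763 with an estimated correlation), with the lymphatic and sinusoidal receptor Lyve1 at 4.28 ± 1.75 and 18.8 ± 10.8. Their median was 0.36 without control 1 and 0.35 without mutant 1.

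Markers of other organs moved with single spleen libraries. Pancreas genes had 18 of 18 above 0 in mutant spleen (median 1.98, adjusted p = 0.0036; 0.763 with an estimated correlation). The amylase gene Amy2a5 read 0.345 ± 0.487 in controls and 8.33 ± 11.6 in mutants (SD, n = 2 each). The pancreas median was -1.83 without mutant 2, 5.69 without mutant 1, -0.56 without control 2 and 4.86 without control 1. Hepatocyte genes had 21 of 23 above 0 (median 0.71, adjusted p = 0.0087; 0.763 with an estimated correlation), at -0.83 without mutant 1, -0.38 without control 2, 1.98 without control 1 and 2.08 without mutant 2. Megakaryocyte and platelet genes had 1 of 18 above 0 (median -0.53, adjusted p = 0.036; 0.763 with an estimated correlation), at 0.22 without mutant 1, 0.04 without control 2, -1.04 without control 1 and -1.57 without mutant 2. Keratinocyte, neuronal, liver mesenchyme and heat shock lists were also called higher in spleen (adjusted p = 0.0356, 0.0452, 0.0356 and 0.0057, each 0.763 with an estimated correlation), with medians of 1.12, 0.89, 0.39 and 0.56. Without control 2 each of these 4 calls was lost, with medians of 0.92, 0.98, 0.61 and 0.46. The keratinocyte median was 0.19 without mutant 2 (call lost) and 2.57 without mutant 1, and the heat shock call was lost without mutant 1 (0.39). The neuronal call was also lost without control 1 (0.77), mutant 1 (0.66) or mutant 2 (0.56), and the liver mesenchyme call without mutant 2 (0.45), with medians of 0.26 and 0.65 without control 1 and mutant 1. Adjusted over the list alone, these 4 lists gave 0, 1, 2 and 1 genes higher and 0, 1, 1 and 0 lower.

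Single autosomal genes with the smallest p in spleen included Klf15, a glucocorticoid-responsive transcription factor, at 3.24 ± 0.287 in controls and 55.6 ± 8.53 in mutants (SD, n = 2 each; log2 fold change 3.90, SE 0.30, limma adjusted p = 0.0746; DESeq2 adjusted p = 1.4e-21). The decoy interleukin receptor Il1r2 read 10.9 ± 0.560 and 102 ± 38.04 (log2 fold change 3.12, limma adjusted p = 0.136), the angiotensin receptor Agtr1a 29.5 ± 2.12 and 186 ± 2.70 (2.64, limma adjusted p = 0.124) and the glycosyltransferase Galnt15 2.52 ± 1.42 and 52.1 ± 0.183 (4.21, limma adjusted p = 0.124). Stfa1, a protease inhibitor of neutrophils, read 211 ± 174 and 2.37 ± 1.65 (-6.03, SE 0.68, limma adjusted p = 0.136). In liver Stfa1 read 66.7 ± 7.56 in controls and 0.962 ± 0.390 in mutants (-5.54, SE 0.28, limma adjusted p = 0.0903; DESeq2 adjusted p = 2.1e-44). Stfa1 belongs to a family of near-identical copies, so its level is uncertain.

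In mutant liver, camera called stress, matrix, endothelial and immediate early genes higher and interferon genes lower. The liver mesenchyme, smooth muscle and adipogenic lists were not called there (camera adjusted p = 0.766 for each). Setdb2, a histone methyltransferase, read 30.0 ± 8.78 in controls and 544 ± 66.5 in mutants (SD, n = 2 each; log2 fold change 4.18, SE 0.29, limma adjusted p = 0.106; DESeq2 adjusted p = 2.0e-22). Its neighbour on chromosome 14, Phf11c, read 8.46 ± 2.25 and 174 ± 4.80 (4.31, SE 0.25, limma adjusted p = 0.0979). The adrenergic receptor Adra2a read 2.10 ± 0.181 and 27.2 ± 3.12 (3.41, limma adjusted p = 0.106) and Fibin 0.288 ± 0.0475 and 10.02 ± 2.04 (3.73, limma adjusted p = 0.129). Stress and apoptosis genes had 12 of 17 above 0 (median 0.34, camera adjusted p = 0.0066; 0.815 with an estimated correlation), 2 of which rose adjusted over the list alone, with Ddit4, an inhibitor of mTOR signalling, at 7.42 ± 1.32 and 124 ± 56.2 (DESeq2 adjusted p = 1.2e-15). The stress median was 0.17 without mutant 1, 0.61 without control 1 and 0.87 without mutant 2. Immediate early and heat shock genes had 9 of 12 above 0 (median 0.80, adjusted p = 0.0038; 0.815 with an estimated correlation), 4 of which rose adjusted over the list alone, with Fos at 3.18 ± 0.449 and 12.0 ± 6.16 and Nr4a1 at 1.62 ± 1.12 and 10.7 ± 5.92. Their median was 0.35 without control 1 and 1.33 without control 2.

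Genes activated by p53 had 18 of 23 above 0 in mutant liver (median 0.16, adjusted p = 0.0291; 0.815 with an estimated correlation), 2 of which rose adjusted over the list alone. The stress sensor Sesn2 read 14.7 ± 2.09 and 57.7 ± 20.6, the cell cycle inhibitor Cdkn1a 21.5 ± 4.09 and 77.0 ± 41.0, and the death receptor Fas 13.2 ± 0.393 and 6.66 ± 0.533 (SD, n = 2 each). The p53 call was lost without control 2 (0.09) or mutant 1 (0.12), and its median was 0.38 without control 1 and 0.41 without mutant 2. Interferon response genes had 5 of 20 above 0 (median -0.25, adjusted p = 0.0045; 0.815 with an estimated correlation), with the signal transducer Stat2 at 63.1 ± 1.15 and 38.4 ± 13.4, lost without control 1 (-0.13) or mutant 2 (-0.19). Fibroblast and matrix genes had 18 of 21 above 0 (median 0.36, adjusted p = 0.0038; 0.815 with an estimated correlation), lost without control 1 (0.21) or mutant 1 (0.29). Endothelial genes had 11 of 12 above 0 (median 0.30, adjusted p = 0.0169; 0.815 with an estimated correlation), with Lyve1 at 107 ± 2.96 and 194 ± 13.2, lost without control 1 (0.14) or mutant 2 (0.24), and at 0.53 without control 2. The last 3 lists had 0 genes past limma over all genes and 0 adjusted over the list alone.

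In mutant fibroblasts, camera called inflammatory genes lower and ribosomal protein genes slightly higher. Of the 10 splits of the 6 fibroblast libraries, 7, the real one included, called at least 7 lists. The number of lists called in fibroblasts therefore cannot be credited to genotype. Which lists each split called was not compared, so the splits do not decide on any single list. Inflammatory and secreted factors had 0 of 13 above 0 (median -0.44, camera adjusted p = 0.0022; 0.772 with an estimated correlation), with the chemokines Cxcl5 at 88.1 ± 12.4 in controls and 61.8 ± 17.7 in mutants and Ccl2 at 81.1 ± 11.0 and 65.2 ± 33.2 (SD, n = 3 each). That call was lost without control 3 (-0.25), mutant 1 (-0.38) or mutant 2 (-0.16), and the median was -0.72 without mutant 3. Autosomal ribosomal protein genes had 26 of 27 above 0 (median 0.09, adjusted p = 2.5e-04; 0.779 with an estimated correlation), lost without mutant 2 (0.02). Matrix genes had 16 of 24 above 0 (median 0.13, adjusted p = 0.018; 0.772 with an estimated correlation), with Postn, a matrix protein of fibroblasts, at 1230.6 ± 97.47 and 2125.5 ± 891, and their median was -0.00 without mutant 1, 0.17 without control 3 (call lost), 0.21 without control 2 and 0.27 without mutant 2. Sterol and lipid genes had 3 of 15 above 0 (median -0.27, adjusted p = 0.0011; 0.772 with an estimated correlation), with Cpt1a, which brings fatty acids into mitochondria, at 76.3 ± 0.504 and 52.9 ± 12.8. Their call was lost without control 1 (-0.12) or mutant 1 (-0.14), and the median was -0.53 without control 3 and -0.57 without mutant 2. Nuclear noncoding RNAs had 3 of 11 above 0 (median -0.19, adjusted p = 0.018; 0.772 with an estimated correlation), with Gas5 at 67.6 ± 4.80 and 50.6 ± 4.35, lost without control 1 (-0.12), mutant 1 (-0.20) or mutant 3 (-0.00), and at -0.32 and -0.37 without control 3 and mutant 2. None of these 5 lists had a gene past limma over all genes or adjusted over the list alone. Of single autosomal genes, the cadherin Pcdh7 read 186 ± 20.4 and 102 ± 20.8 and the collagen receptor subunit Itga11 34.6 ± 11.6 and 88.5 ± 22.7 (limma adjusted p = 0.9997 for each).

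Of the fixed lists, camera called 7 of 35 tested in fibroblasts, 17 of 42 in spleen, 9 of 40 in liver and 15 of 40 in brain. None of these calls held with an estimated correlation. That test takes its degrees of freedom from the few libraries, so a lost call does not by itself point to correlation among genes. The escape list in fibroblasts had an estimated correlation of -0.0034, below the preset 0.01, and still gave adjusted p = 0.0595 by that test.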

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

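The list of stress and apoptosis genes lay on opposite sides of 0 in liver and brain, which brought it here. Its median log2 fold change, mutant against control, was 0.34 in liver (camera adjusted p = 0.0066) and -0.12 in brain (camera adjusted p = 0.0149), a gap of 0.4543. With an estimated correlation the adjusted p was 0.815 in liver and 0.493 in brain, and the brain call was lost without control 2 (adjusted p = 0.106) or mutant 2 (adjusted p = 0.0656). Each mutant liver library lay on the higher side and each mutant brain library on the lower side of its controls. In liver 12 of 17 members lay above 0 and in brain 4 of 17. The difference between liver and brain was not tested.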

How the results depend on the processing

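The DESeq2 tests of Xist were chosen after the limma result was seen. By camera with an estimated correlation the X-linked difference gave p = 0.105 in fibroblasts (0.0517), 0.166 in spleen (0.106) and 0.0717 in liver (0.0547). The estimated correlations were 0.047 in fibroblasts, 0.0098 in spleen and 0.0026 in liver. Those of spleen and liver lay below the preset 0.01, so correlation among genes does not account for the calls lost there. Tested by fry against no change, with correlation among genes allowed for, X-linked genes gave p = 0.278 in fibroblasts and 0.161 in spleen. Without escape and inactivation centre genes the difference was 0.0959 in spleen (camera p = 0.0583 at the preset correlation) and 0.0441 in liver (p = 0.0629). With no filter on low values it was 0.0021 in fibroblasts (camera p = 0.393 at the preset correlation), 0.0182 in spleen (p = 0.0929) and 0 in liver (p = 0.717), the per-library level difference was 0.0264 in liver and 0.0945 in brain, the escape gap was 0.438 in liver and 0.387 in brain, Xist in spleen kept -3.90 with adjusted p = 0.005, limma called 22 genes in spleen, 11 in liver and 13 in brain, and 3 fixed lists were called in fibroblasts. An adjusted p below 0.1 gave 1 gene in spleen and 2 in liver, since the threshold was looser. DESeq2 called 3 genes in fibroblasts, 182 in spleen, 211 in liver and 41 in brain, and gave Xist log2 fold changes of -3.53, -3.73 and -1.67 in fibroblasts, spleen and liver, each past the threshold. A pseudocount of 5 gave Xist -3.01 in fibroblasts and a per-library level difference of 0.141 in brain. For the remainder the cause was not tested.

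With the replicate number as a block, limma called 356 genes in spleen (268 higher, 88 lower) and 60 in liver (46 higher, 14 lower), Xist was -3.90 in spleen and -1.62 in liver, both past the threshold, and the X-linked set difference in spleen was 0.106 (camera p = 0.0908 at the preset correlation). Correlations of deviations between libraries of the same number were -0.08, 0.432 and 0.0231 in fibroblasts. There control 1 went best with mutant 2 (0.255) and control 3 with mutant 1 (0.539). The same correlations were -0.0257 in spleen, 0.585 in liver and 0.0783 in brain. The numbers were not taken as pairs in the main tests, since same-number libraries did not go together in each tissue. In liver they did, and satellite-repeat genes took the largest share of reads in the library numbered 1 of each tissue and genotype. A factor shared by number is thus not excluded, and the blocked counts stand beside the main ones.

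Leaving out each library in turn leaves 1 library in an arm of the organs, and the lone library is assumed to vary like the others. The X-linked set difference then ranged from 0.0125 to 0.121 in fibroblasts, 0.0336 to 0.148 in spleen and 0.00634 to 0.134 in liver, and stayed past the threshold in brain. Xist ranged from -4.13 to -2.97 in fibroblasts and -4.49 to -3.31 in spleen. The escape gap ranged from 0.103 to 0.197 in fibroblasts, 0.113 to 0.446 in spleen, 0.246 to 0.524 in liver and 0.243 to 0.412 in brain, and genes called by limma from 0 to 177 in spleen and 6 to 109 in brain. List medians that changed sign ranged from -0.0012 to 0.274 for matrix genes in fibroblasts, -0.0427 to 0.621 for X-linked blood and immune genes, -1.57 to 0.223 for megakaryocyte genes, -0.833 to 2.08 for hepatocyte genes and -1.83 to 5.69 for pancreas genes in spleen, and -0.0313 to 0.983 for choroid plexus genes in brain. The cause was not tested. Of the other settings, 219 values of the comparisons kept their side of the threshold or stayed within their spread, while 18 moved further, 6 gained a call and 11 lost theirs. For the lists 399 stayed and 19 lost their call, and for named genes 7460 stayed, 175 moved further, 194 gained a call and 2 lost theirs. Depth limits genes near the signal of 1 read, 0.0343 to 0.0751.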

Other observations

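The glucocorticoid, fasting, fat oxidation and satellite lists here were chosen after the values were seen. So were the tests of loss of an X, Xist left, corticosteroid signalling, handling stress and segregating variants. The clock gene lists were also added after the data were examined, with their prediction written before its test. Genes induced by glucocorticoids were higher in the organs of mutant pups, with a median log2 fold change of 1.53 in spleen (23 of 28 above 0, camera p = 2.6e-21; 0.0168 with an estimated correlation), 1.29 in liver (26 of 29, p = 9.3e-21; 0.0231) and 0.23 in brain (21 of 26, p = 6.4e-11; 0.0207; median 0.36 without mutant 2), against -0.12 in fibroblasts (7 of 24, p = 0.279; -0.26 without mutant 1, p = 0.0204, and 0.03 without mutant 2, p = 0.965). Fkbp5, a regulator of the glucocorticoid receptor, had 2.21 in spleen and 0.99 in liver, and Zbtb16, a zinc finger transcription factor, 3.35 and 2.84. In liver, fasting genes had a median of 1.79 (15 of 18 above 0, p = 3.8e-13; 0.0647 with an estimated correlation), against 0.79 in spleen (12 of 17, p = 7.8e-04; 0.219 with an estimated correlation; 0.10 without mutant 1, p = 0.501), 0.05 in brain (6 of 11, p = 0.445) and 0.00 in fibroblasts (5 of 10, p = 0.536), with liver Lpin1 at 4.83, the serine dehydratase Sds at 3.60, Tat at 3.31 and G6pc, which releases glucose, at 2.43. Fat oxidation genes driven by PPAR alpha had a median of -1.003 in liver (0 of 26 above 0, p = 2.7e-12; 0.203 with an estimated correlation), -0.49 without control 2 and -0.26 without mutant 1, with Fabp1 at -1.51, and -0.34 in spleen (4 of 18, p = 0.483), -0.06 in brain (6 of 17, p = 0.142) and 0.00 in fibroblasts (9 of 18, p = 0.956). The glucocorticoid list includes genes already seen to be changed, among them Klf15, Tsc22d3, Pdk4, Il1r2, Hif3a, Ddit4 and Cdkn1a, so its p-values are circular and only describe these libraries.

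Glucocorticoid-responsive genes were higher in 3 organs of mutant pups. Higher immediate early and heat shock genes, looked for as a trace of handling stress at collection, were not seen in brain, where their median was -0.154. Their medians were 0.80 in liver and 0.56 in spleen. Handling would act on the whole pup and the brain prediction was written after the values were seen, so handling stress stays open. Raised corticosteroid or fasting signalling stays open, since the brain median of 0.2337 comes from the list that makes up the pattern and cannot test it, and so does collection at another time of day, with a gap of -1.09 between clock genes of opposite phase in liver, against -0.152 in fibroblasts, -0.164 in spleen and 0.068 in brain. Liver control 2 stood apart on that clock gap at 0.993, against -0.138, -0.556 and -0.299 in control 1, mutant 1 and mutant 2. Each of these explanations is confounded with genotype in these few pups.

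X-linked genes were higher in 1 of 3 mutant fibroblast libraries, mutant 2. The tables argue against loss of an X chromosome in mutants 1 and 3, since their escape genes stood at 0.172 and 0.224 above the control mean, against 0.248 in mutant 2. They also argue against transcript length, GC or expression bias as the whole cause, since the excess was 0.258 before and 0.256 after correction. More Xist left in mutants 1 and 3 was not seen in the reads, since mutant 2 held the most Xist reads of the mutants. On the log2 scale it lay 2.3 above mutant 3, beyond the SD of 0.499 among controls, which argues against this for mutant 3. It lay 0.274 above mutant 1, within that SD, so this stays open for mutant 1. The deleted part is unknown. What set mutant 2 apart stays open, and a difference between animals or cultures was not tested.

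In the organs 3 autosomal pseudogenes, Gm9493, Gm4735 and 3110053B16Rik, were much lower in controls than in mutants. Variants that segregate between the animals rather than follow genotype could account for this, since 11 genes split by at least 2-fold in groupings that mix the genotypes, 8 by replicate number, 5 of them satellite-repeat genes, and 3 by the crossed grouping. Without satellite-repeat genes each grouping had 3, and at a gap of at least 4-fold the grouping by genotype had 1, by number 0 and the crossed grouping 2. With so few genes this stays open, and a link to Xist was not tested. In fibroblasts the 3 genes read 1.202 and 1.405, 5.92 and 6.18, and 3.58 and 3.08 in controls and mutants.

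The 10 splits of the 6 fibroblast libraries are too few for a share under 0.05. The real split gave 0 genes (highest other 1; 10 splits as large), an X-linked difference of 0.0517 (highest other 0.104; 7 splits as large) and 7 lists (highest other 13; 7 splits as large).

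Satellite-repeat genes took the largest share of reads in the library numbered 1 of each tissue and genotype, 3.01% against 0.0184% in mutant spleens and 1.76% against 0.00316% in control livers.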
